A study of Penicillium oxalicum with 9 samples.

How the data were processed

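Transcript levels were measured in mycelia of the filamentous fungus Penicillium oxalicum, in 9 libraries from 3 strains, with 3 libraries per strain. The strains were the wild type 114-2, a strain with the gene clrB deleted and a strain with the gene rcoA deleted. Per the labels' protocols, spores were grown for 22 h at 30 °C in a medium with 2% glucose, and the washed mycelia were then moved for 24 h to a medium whose carbon came from cellulose and wheat bran, at 1% each. The labels do not say whether the 3 libraries of a strain came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

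The deposited table gave FPKM (fragments mapped to a transcript, scaled by its length and by the mapped total of the library) for 9907 genes, computed by the authors, to 2 decimals. Per the labels' protocols, libraries were made from oligo(dT)-selected RNA by cutting cDNA with NlaIII and MmeI into short tags. Such tags come from a fixed site of each transcript, whereas FPKM divides by transcript length. The aligner, the counting, the gene lengths and the genome build are not given in the sources used here. Any length scaling cancels in a ratio of 2 libraries for the same gene, but not between genes, so rankings or sums of FPKM over different genes are uncertain to that extent. Near-identical gene copies may have shared reads, and their values are uncertain to that extent. The table held 3 further columns of per-library values for a strain with no sample among the labels used here, and these were not analysed here.

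Gene descriptions were those the authors deposited beside the FPKM, from KEGG orthology and from the NCBI nr database. They are automated, and a gene can carry several that do not match each other, so a description is a label and not a tested function. Of the 9907 identifiers, 0 matched the 9964 genes of the reference table given for the species (assembly ASM172317v3, strain HP7-1). No coordinates are therefore given, and identifiers are used as the deposited table has them.

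The total depth of each library is unknown, because no counts were used. The sum of FPKM ranged from 776855 to 820648 per library, and between 9597 and 9724 genes had a value above 0. Where whole reads were counted, low FPKM values are whole multiples of what 1 read is worth. Ratios of low values between libraries therefore pile up at the ratio of these worths, which is the inverse of the ratio of their depths. The estimator of this pile-up was chosen after the data were seen, by its recovery on simulated whole reads, where other versions did less well. At the lower 2 of 3 simulated depths it came within 5% of true ratios from 0.6 to 1.6 in at least 18 of 20 draws, and at the highest in at least 13. A true ratio of 2 gave a value within 10% of 1 in 10 to 15 of 20 draws. Against wild type replicate 1 it lay between 0.989 and 1.01 in 6 of the other libraries and at 0.493 in wild type replicate 3 and clrB deletion replicate 3. Relative depth was therefore left open by a factor of about 2.

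Genes with a mean FPKM of at least 1 over the 9 libraries were tested, 9097 in all. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per strain in a single fit over the 9 libraries and an intensity trend in the empirical Bayes step. Tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold. Fold changes on this scale understate the change of low genes, and a fold of means is given only where both means reached 1 FPKM. The 3 comparisons were each deletion against wild type and the clrB deletion against the rcoA deletion. The last is also the test of the difference between both deletion effects, since these share the wild type libraries.

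The comparisons, tests, rule for named genes, 17 gene lists and alternatives were fixed before the data were examined, and the lists are word patterns searched in the descriptions. A list needed 5 tested members, which left 16 for testing. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Lists share members: cellulose and hemicellulose degradation share 9, and starch degradation and fungal cell wall share 6. Gene ontology terms with at least 10 tested genes, 147 in all, and a list of sugar symporters were added after the data were seen.

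Genes were named by a fixed rule. For each deletion these were called genes whose 3 deletion libraries all lay on 1 side of the 3 wild type libraries, with a mean of at least 10 FPKM in 1 group and a functional description. Of these, the 6 largest rises and the 6 largest falls were taken, or 4 each way for the comparison of both deletions. Descriptions were not required of the other named genes. From each list the called member with the highest mean was added, or the 3 highest for the lists of cellulose, hemicellulose and starch degradation, sugar transport, secondary metabolism and asexual development. For genes called in both deletions, the 3 with the largest smaller change were taken for each sign pattern. The deleted genes and a set of fixed loci were always included. The fixed loci for amyR and Amy15A were left out under those names because their deposited descriptions (an oligo-1,6-glucosidase among others, and an alpha-amylase) were of another protein type. Genes named outside this rule are marked as chosen after their values were seen.

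The procedure was tested on simulated data with 200 changed genes among 9097, over 20 draws. For the clrB comparison, simulated with each gene's raw standard deviation, 82.2% of changes of 1 log2 unit and 96.3% of changes of 2 log2 units were recovered, and false calls made up 4.84% of calls. For the rcoA comparison these were 81.4%, 96.9% and 5.40%. Simulated with moderated standard deviations, they were 89.0%, 98.2% and 4.95% for clrB and 88.2%, 99.0% and 4.22% for rcoA. Single draws had false shares of up to 8.61%, so in these simulations the share was held near 5% on average only. The simulations gave all libraries of a gene the same spread and drew genes independently. Changed genes were drawn only from those at about 10 FPKM or more in wild type. Recovery of lower genes was therefore not tested. Nor was a setting tested in which most genes change, although 64.5% of genes were called in the rcoA comparison. In the data the standard deviation of log2 deviations from the group mean was 0.378 in clrB deletion replicate 2. It was 0.107 to 0.253 in the other libraries. The simulations therefore do not show that false calls are held near 5% in the clrB comparison. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, 3 scalings, fits with 2 groups, a fit with the replicate number as a block, no intensity trend, leaving out each library in turn and, for the lists, members limited to a mean of 5 FPKM. Tests on counts were planned only for a table with counts and were not run.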

Results

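The data comprised FPKM of 9907 genes in 9 libraries of Penicillium oxalicum, a fungus that secretes plant cell wall degrading enzymes, grown for 24 h on wheat bran and cellulose. There were 3 libraries each of the wild type, the clrB deletion and the rcoA deletion. ClrB is a transcriptional activator of cellulase genes, and RcoA is a corepressor of the Tup1 family. Values are group means of FPKM ± SD with n = 3 throughout, and log2 changes are given with their standard error (SE). The comparisons ask which transcripts depend on each regulator on a cellulosic medium.

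The deleted genes were examined first. The gene described as ClrB, PDE_05999, had 185 ± 19.3 FPKM in wild type and 0.10 ± 0.017 in the clrB deletion, where the 3 libraries read 0.11, 0.11 and 0.08. It was also lower in the rcoA deletion, at 63.3 ± 6.12 (log2 change -1.53, SE 0.11, adjusted p = 3.17e-06). The labels do not give the locus of rcoA, and 4 genes were described as TUP1. Of these PDE_01024 stood at 67.8 ± 2.64 in wild type, 67.3 ± 1.29 in the clrB deletion and 2.71 ± 0.651 in the rcoA deletion. The others read 19.3 ± 1.23 (PDE_08941), 25.1 ± 0.435 (PDE_00660) and 7.36 ± 1.51 (PDE_07598) in the rcoA deletion, against 31.2 ± 2.33, 18.8 ± 1.12 and 4.84 ± 0.701 in wild type.

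The libraries separated by strain. The first principal component held 75.3% of the variance and set the rcoA deletion apart, and the second held 15.2% and ordered wild type below the clrB deletion. Correlations of log2 values within the wild type were 0.985 to 0.991 and within the rcoA deletion 0.984 to 0.993. Replicate 2 of the clrB deletion stood apart from replicates 1 and 3, at 0.946 and 0.957, while those correlated at 0.991. No library held values identical to another.

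**Figure D1:**
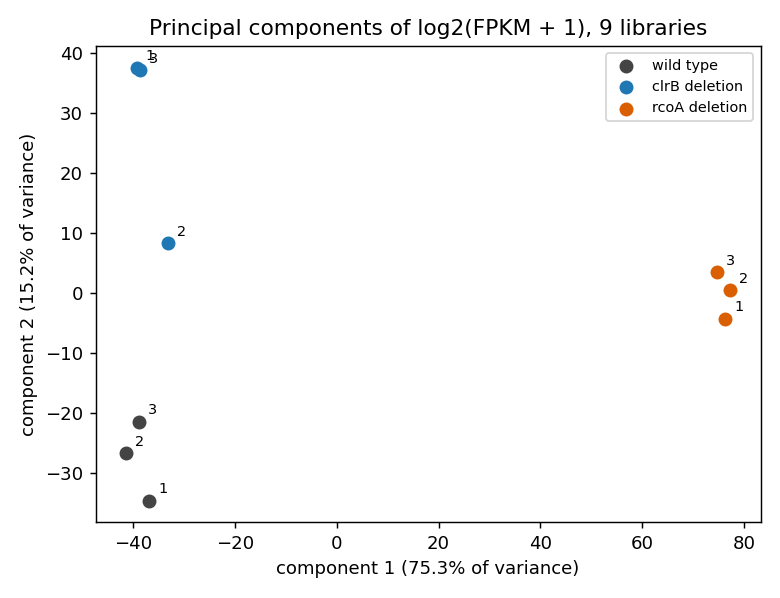
Principal components 1 and 2 of log2(FPKM + 1) over the 9097 tested genes, 1 point per library, numbered by replicate. The rcoA deletion lies to the right at 74.7 to 77.3 on component 1, and clrB deletion replicate 2 lies at 8.28 on component 2, below replicates 1 and 3 at 37.6 and 37.2.

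Among genes that met the naming rule, those that fell furthest in the clrB deletion were genes of cellulose use, besides the deleted gene clrB. The cellulose monooxygenase Cel61A (PDE_05633), an enzyme that cuts cellulose by oxidation, went from 4244 ± 316 FPKM in wild type to 4.25 ± 1.05 (log2 change -9.68, SE 0.29, adjusted p = 1.38e-07). Cellobiohydrolase II (Cel6A, PDE_07124) went from 3715 ± 607 to 11.5 ± 1.93, which is 323-fold lower. The endoglucanase PDE_09226 was 237-fold lower, the cellodextrin transporter cdt-c (PDE_00607) 176-fold lower and the beta-glucosidase Bgl2 (PDE_00579) 125-fold lower. All of these changes lay far outside the spread between libraries, with adjusted p of 2.39e-07 or less.

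Of the 43 tested members of the cellulose degradation list, 24 fell, 1 rose and 18 were not called. Adjusted over the list alone, 26 fell and 2 rose. The list was lower by camera (adjusted p = 8.14e-19), but not with an estimated correlation (adjusted p = 0.0883). The cellobiohydrolase Cel7A-2 (PDE_07945), the called member with the highest mean FPKM, fell 14.3-fold from 6744 ± 1078 to 471 ± 298 FPKM, and the endoglucanase Cel7B (PDE_07929) fell 28.8-fold from 2068 ± 664 to 71.7 ± 44.0. Without clrB deletion replicate 2 these folds were 22.4 and 44.6. The beta-glucosidase Bgl1 (PDE_02736) was not called, at 616 ± 40.9 and 906 ± 509, where replicate 2 read 1490.4 and replicates 1 and 3 read 560 and 667.

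**Figure D2:**
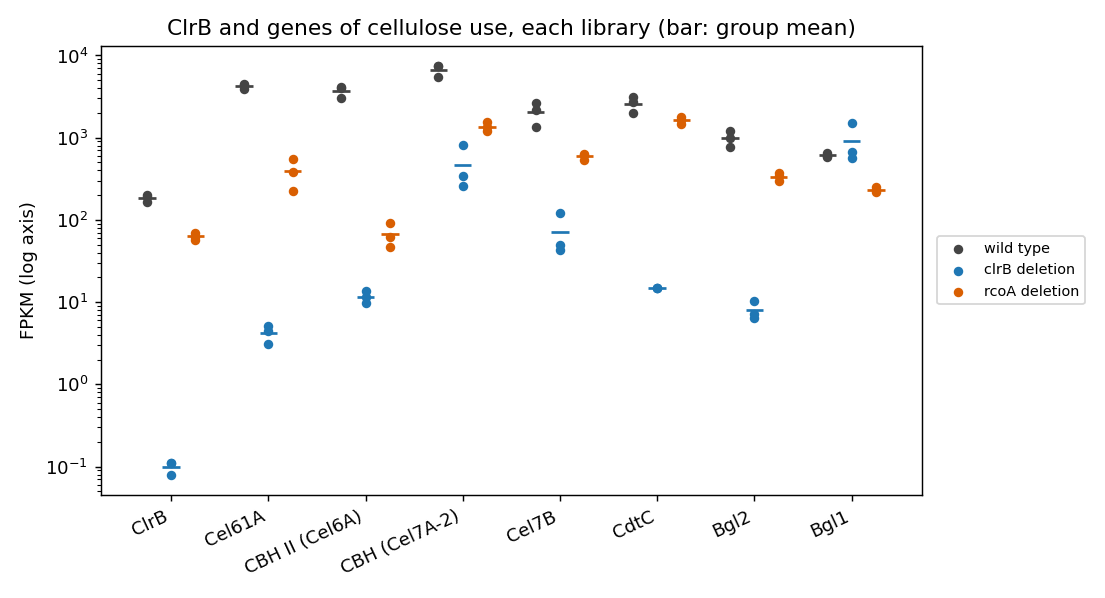
FPKM on a log axis of ClrB and 7 genes of cellulose use, 1 point per library, coloured by strain, with a bar at each group mean. Cel61A has a mean of 4244 in wild type, 389 in the rcoA deletion and 4.25 in the clrB deletion, and Bgl1 is the gene whose clrB deletion mean, 906, lies above the wild type mean, 616.

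In the hemicellulose, pectin and starch lists more of the called members fell than rose. Among 83 hemicellulose genes 29 fell and 6 rose (31 and 9 adjusted over the list alone), with falls of the GH10 xylanase PDE_08094 (15.7-fold, to 125 ± 107 FPKM), the GH45 protein PDE_07928 (38.7-fold) and the feruloyl esterase PDE_06649 (15.1-fold). Without clrB deletion replicate 2 these folds were 30.8, 75.6 and 25.1. PDE_07928 is also described as an endoglucanase, and 9 of the 83 genes are in the cellulose list too. Of 27 pectin genes 11 fell and 0 rose (12 and 1 over the list alone), the one with the highest mean being a rhamnogalacturonan acetylesterase (PDE_02093, 1.73-fold). Of 23 genes in the starch list, 6 of them shared with the fungal cell wall list, 5 fell and 0 rose (7 and 0 over the list alone). The other 18 were not called, and the median log2 change of this list was -0.0738, against -1.42 for the cellulose list. Those that fell included the glucoamylase Amy15A (PDE_09417), which releases glucose from starch, from 1679 ± 188 to 1092 ± 75.1, a starch binding domain protein (PDE_01354, 5.29-fold) and an alpha-glucosidase (PDE_00400, 2.34-fold). Camera called the hemicellulose, pectin and starch lists lower (adjusted p = 3.21e-07, 1.22e-05 and 0.0095). With an estimated correlation the adjusted p were 0.241, 0.247 and 0.145. The sugar transport list had 4 members, too few to test, of which 2 fell, also over the list alone: cdt-c and CdtD (PDE_00753, 4.20-fold, or 7.20-fold without clrB deletion replicate 2).

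Genes also rose in the clrB deletion. A gene described as an HSP20 family protein, a small heat shock chaperone (PDE_02505), went from 39.8 ± 4.56 to 1479 ± 292 FPKM (37.2-fold, log2 change 5.17, SE 0.21, adjusted p = 1.18e-06). The Hsp70 exchange factor Fes1 (PDE_01090) rose 16.2-fold and a mitochondrial alternative oxidase (PDE_08849), which bypasses part of the respiratory chain, 9.91-fold. Rises of 7.85-fold and 5.73-fold were found for genes described as a threonine aldolase (PDE_08440) and as a zinc transporter (PDE_05715). PDE_07434, described as TIM23 among other names, went from 4.14 ± 2.15 to 50.3 ± 37.8, with replicate 2 at 7.83 against up to 6.40 in wild type, and its call was lost under 5 of 19 alternatives. Of 37 secondary metabolism genes 10 rose and 0 fell (16 and 1 over the list alone). Those with the highest means were described as a trichodiene synthase (PDE_01717, 1.93-fold), both a solute carrier and an aflatoxin B1 aldehyde reductase (PDE_00183, 1.48-fold), and a sterigmatocystin type methyltransferase (PDE_01069, 2.93-fold). These calls were lost under 3, 5 and 10 of 19 alternatives, each of them without clrB deletion replicate 3. Of 25 glycolysis genes 8 rose and 0 fell (also 8 and 0 over the list alone), among them a fructose-bisphosphate aldolase (PDE_04802, 1.49-fold). Camera called both lists higher (adjusted p = 0.0095 and 0.00677), while with an estimated correlation the adjusted p was 0.452 for each. Without clrB deletion replicate 1 the glycolysis list was not called (adjusted p = 0.0611).

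The asexual development list had 5 members, of which 2 rose (3 adjusted over the list alone), with no call for the list (camera adjusted p = 0.395). The regulator of conidiation BrlA (PDE_00087) stood at 24.9 ± 5.79 in wild type and 101 ± 60.3 in the clrB deletion, where the replicates read 149, 33.4 and 121. FlbD (PDE_03008) rose 1.80-fold (adjusted p = 0.0485), a call lost under 14 of 19 alternatives. The remaining lists had no camera call, with adjusted p from 0.202 to 0.907. Higher and lower members numbered 14 and 13 of 80 for fungal cell wall (17 and 17 adjusted over the list alone), 12 and 6 of 48 for secreted proteases (13 and 8), 1 and 2 of 12 for cytochrome P450 (2 and 2) and 6 and 3 of 152 for ribosomal proteins (3 and 2). They numbered 3 and 4 of 63 for ER folding and secretion (3 and 4), 8 and 1 of 46 for respiration (8 and 1), 12 and 6 of 65 for stress proteins (13 and 6), 4 and 3 of 68 for DNA replication and histones (0 and 2) and 6 and 8 of 49 for nitrogen uptake (7 and 8). For fungal cell wall, cytochrome P450 and ER folding and secretion the median and mean log2 change lay above 0 while camera ranked the list downward. Members called in these lists included a peptidoglycan binding domain protein (PDE_06124, 1.78-fold higher), an aspergillopepsin (PDE_07927, 1.83-fold lower), the folding stress activator Hac1 (PDE_01436, 1.75-fold lower) and an oligopeptide transporter (PDE_05534, 2.07-fold lower). Others were a ribosomal protein L25 (PDE_05477, 1.45-fold higher), a succinate dehydrogenase subunit (PDE_07264, 1.37-fold higher), PDE_06972, described as a cytochrome P450 (1.68-fold lower), and a DNA polymerase alpha-associated helicase (PDE_07983, 1.36-fold lower). The xylanase activator XlnR (PDE_07674) fell from 69.0 ± 8.57 to 49.4 ± 8.55 FPKM (adjusted p = 0.036), and the carbon catabolite repressor CreA (PDE_03168) was not called, at 335 ± 27.4 and 391 ± 5.95.

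In all, 1230 genes were higher and 757 lower in the clrB deletion, of 9097 tested with limma, and 205 and 230 of these changed at least 2-fold on the log2(FPKM + 1) scale. The share of calls that were higher, 61.9%, was 45.7% with trimmed mean factors, 49.9% with equal medians and 49.2% with quantile normalization, so the split of directions depended on the scaling. The total of 1987 calls became 3409 without clrB deletion replicate 2, 724 without clrB deletion replicate 3, and 873, 1075 and 1283 without wild type replicates 1, 2 and 3. Without clrB deletion replicate 2, which stands apart, 1909 of the 1987 calls were kept. Lower and higher members then numbered 27 and 4 for cellulose, 40 and 15 for hemicellulose, 14 and 2 for pectin, 8 and 4 for starch, 2 and 19 for secondary metabolism and 0 and 14 for glycolysis. They numbered 22 and 23 for cell wall, 10 and 17 for proteases, 3 and 5 for cytochrome P450, 8 and 12 for ER folding, 1 and 10 for respiration, 10 and 17 for stress proteins, 8 and 9 for DNA replication and histones, 15 and 9 for nitrogen uptake, 0 and 3 for asexual development and 3 and 0 for sugar transport. The ribosomal proteins, 43 higher and 5 lower, were called higher (camera adjusted p = 0.000205, 0.64 with an estimated correlation). Of the 41 genes the naming rule gave with a call in this comparison, 25 kept it under all 19 alternatives. The other 16 lost it in at least 1, and each of them without clrB deletion replicate 3: BrlA, FlbD, XlnR, Amy15A, PDE_00183, PDE_01069, PDE_01436, PDE_01717, PDE_02093, PDE_02342, PDE_03882, PDE_04802, PDE_05534, PDE_07434, PDE_07927 and PDE_07983.

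**Figure D3:**
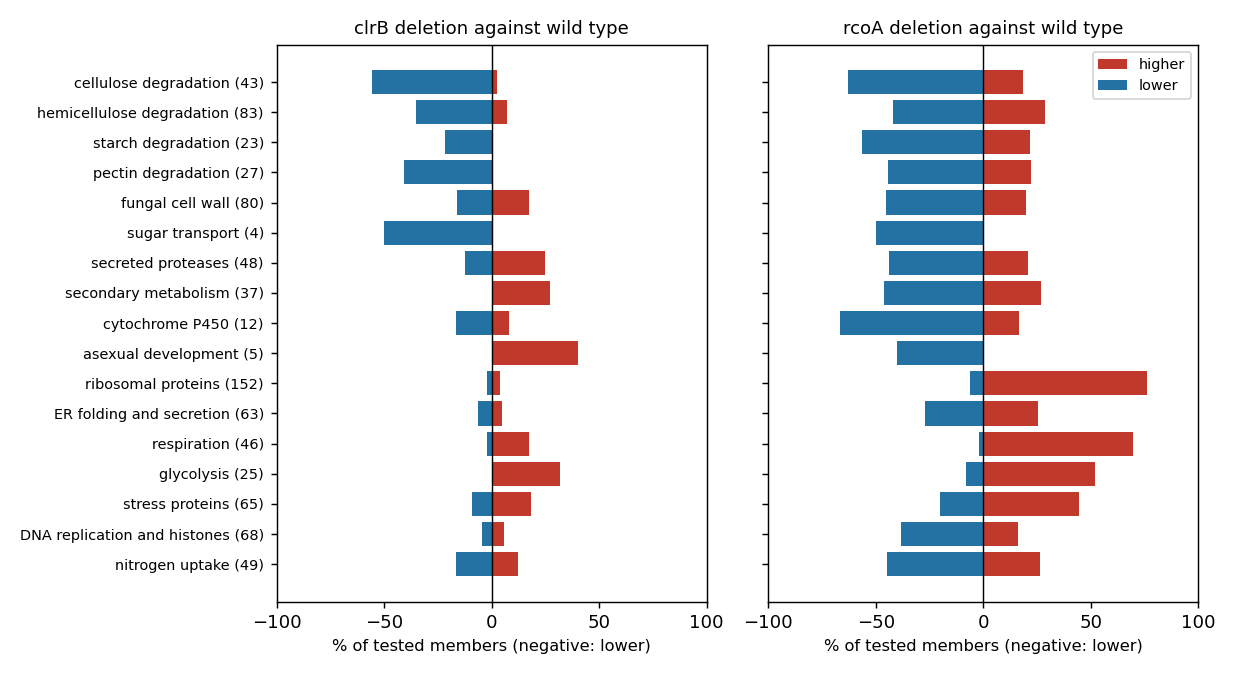
Percent of the tested members of each list, with their number in brackets, that were called higher (red, to the right) or lower (blue, to the left) in each deletion against wild type. Of the 43 cellulose degradation genes 24 were lower in the clrB deletion and 27 in the rcoA deletion, and of 152 ribosomal protein genes 6 and 116 were higher.

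The rcoA deletion changed more genes, with falls and rises over several orders of magnitude. A gene described as 4-hydroxyphenylpyruvate dioxygenase, an enzyme of tyrosine breakdown (PDE_09761), went from 4620 ± 701 to 7.55 ± 3.00 FPKM (612-fold lower, log2 change -9.14, SE 0.39, adjusted p = 1.73e-07). Genes described as an indoleamine 2,3-dioxygenase (PDE_02454, 373 ± 31.6 to 0.393 ± 0.023), a trichodiene synthase (PDE_01717, 116 ± 30.6 to 0.02 ± 0.035) and an O-methyltransferase (PDE_09244, 113 ± 22.0 to 0.063 ± 0.023) fell to near 0. PDE_03255 and PDE_01057, described as a nascent polypeptide complex subunit and a hydroxymethylbilane synthase, fell 309-fold and 160-fold. A putative cutinase (PDE_04915), an esterase for plant cuticle, rose 162-fold from 20.04 ± 3.12 to 3237 ± 674 (log2 change 7.26, SE 0.22). Rises of 238-fold, 184-fold, 96.0-fold and 54.6-fold were found for PDE_07004, described as an enoyl-CoA reductase, the alternative oxidase PDE_08849, the HSP20 gene PDE_02505 and the putative chitinase PDE_01573. PDE_04249, described as a hydroxymethyltransferase, went from 0.893 ± 0.186 to 95.1 ± 7.20.

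Lists of ribosomal proteins, respiration, glycolysis and stress proteins were called higher in the rcoA deletion, though not with an estimated correlation. Of 152 ribosomal protein genes 116 rose and 9 fell (117 and 9 over the list alone), of 46 respiration genes 32 rose and 1 fell, and of 25 glycolysis genes 13 rose and 2 fell, both unchanged in number over the list alone. Examples were the ribosomal protein S27Ae (PDE_04897, 2.02-fold), a succinate dehydrogenase subunit (PDE_07264, 2.11-fold) and the aldolase PDE_04802 (2.17-fold). Of 65 stress proteins 29 rose and 13 fell, also 29 and 13 over the list alone, with the HSP20 gene PDE_00175 11.9-fold higher at 3733 ± 1100. Camera called the lists higher (adjusted p = 3.57e-10, 7.81e-07, 0.0134 and 0.0157 in that order). With an estimated correlation the adjusted p were 0.476, 0.468, 0.468 and 0.468. The stress list was not called with quantile normalization (adjusted p = 0.0701).

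Cellulose genes went both ways in the rcoA deletion, as did the tested genes at large, of which 3104 of 9097 fell and 2762 rose. Of 43 members 27 fell and 8 rose, the same numbers over the list alone, and camera called the list lower (adjusted p = 0.0194), but not with an estimated correlation (adjusted p = 0.468). Cel7A-2 fell 4.95-fold, Cel61A 10.9-fold, Cel6A 55.6-fold, Cel7B 3.47-fold, Bgl1 2.65-fold and Bgl2 2.94-fold. The endoglucanase PDE_06439 rose 4.54-fold, from 283 ± 61.5 to 1283 ± 61.6. Of 83 hemicellulose genes 35 fell and 24 rose, also over the list alone. PDE_07928 and PDE_08094 fell 5.27-fold and 6.03-fold, and xylanase 2 (PDE_04478) rose 9.53-fold. Of 23 starch genes 13 fell and 5 rose (14 and 6 over the list alone). Amy15A rose 1.63-fold, while a chitin binding domain protein (PDE_03292) and an alpha-amylase (PDE_01201) fell 9.15-fold and 2.77-fold. PDE_03292 is also described as a glucan endo-1,3-alpha-glucosidase, so this list does not hold starch genes alone. In the sugar transport list 2 of 4 fell, also over the list alone: cdt-c fell 1.59-fold and cdt-g (PDE_09395) went from 29.0 ± 1.13 to 21.2 ± 2.19. CreA rose 2.31-fold and XlnR fell 2.16-fold.

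Secondary metabolism genes also went both ways, 17 of 37 lower and 10 higher (17 and 11 over the list alone). The counts in this paragraph stand beside 3104 lower and 2762 higher among all 9097 tested genes. A gene described among other names as a naphthopyrone polyketide synthase (PDE_08155) fell 12.9-fold, the methyltransferase PDE_02119 fell 4.65-fold, and an aldehyde reductase (PDE_03369) rose 10.4-fold. Of 5 asexual development genes 2 fell, also over the list alone, both described as scytalone dehydratase, an enzyme of melanin synthesis: PDE_04496 from 45.4 ± 9.97 to 0.48 ± 0.052, and PDE_09236, listed at 0 in all rcoA libraries. BrlA (PDE_00087) stood at 13.1 ± 0.652, against 24.9 ± 5.79 in wild type, and was not called (limma adjusted p = 0.136). It was called without clrB deletion replicate 2 and in a fit of the wild type and rcoA libraries alone. Lower and higher members numbered 12 and 6 of 27 for pectin, with the polygalacturonase PDE_03218 5.25-fold higher, and 36 and 16 of 80 for fungal cell wall, with a glucanosyltransferase (PDE_06441) 3.20-fold higher. They numbered 21 and 10 of 48 for secreted proteases, with a deuterolysin (PDE_07936) 1.94-fold higher, and 8 and 2 of 12 for cytochrome P450, with PDE_06972 3.45-fold higher. For ER folding and secretion they numbered 17 and 16 of 63, with a disulfide isomerase (PDE_06215) 1.67-fold lower, and camera ranked this list upward while its median and mean lay below 0. For DNA replication and histones they numbered 26 and 11 of 68, with histone H4.1 (PDE_00232) 1.34-fold lower, and for nitrogen uptake 22 and 13 of 49, with PDE_05534 7.81-fold lower. Adjusted over the list alone the numbers were 17 and 15 for ER folding, 26 and 10 for DNA replication and histones, 24 and 13 for nitrogen uptake and the same as above for pectin, cell wall, proteases and cytochrome P450. None of the lists in this paragraph or the hemicellulose and starch lists passed camera (adjusted p from 0.124 to 0.932), though cytochrome P450 did without clrB deletion replicate 2 (0.0349) and in a fit of the wild type and rcoA libraries alone (0.0394). With all libraries its adjusted p = 0.468 with an estimated correlation.

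In all, 2762 genes were higher and 3104 lower in the rcoA deletion, 64.5% of those tested, and 1101 and 1358 of these changed at least 2-fold on the log2(FPKM + 1) scale. The share of calls that were higher, 47.1%, was 49.9% with trimmed mean factors, 52.9% with equal medians and 54.0% with quantile normalization, so the direction of the majority turned with the scaling. Of the 53 genes the naming rule gave with a call in this comparison, 49 kept it under every alternative in which they were tested. These were 19 for each gene but PDE_09236, which was tested in 18. PDE_00232, PDE_02342, PDE_07598 and PDE_07936 lost it in at least 1.

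The deletions were compared directly. PDE_03255, PDE_09761, PDE_01717 and PDE_02454 were the genes furthest above the rcoA deletion in the clrB deletion, with log2 differences of 8.78, 8.76, 7.75 and 7.44. The cutinase PDE_04915, cdt-c, Cel61A and PDE_04128, described as a cysteine desulfurase, were furthest below, with -7.62, -6.69, -6.15 and -6.11 (adjusted p of 7.49e-07 or less). Cellulose degradation was lower in the clrB deletion than in the rcoA deletion (26 lower and 9 higher of 43, 27 and 10 adjusted over the list alone, camera adjusted p = 0.000159), but not with an estimated correlation (adjusted p = 0.538). Lower too were ribosomal proteins (104 and 9 of 152, 105 and 9 over the list alone, adjusted p = 1.99e-10), respiration (31 and 1 of 46, 32 and 1 over the list alone, 2.77e-08) and stress proteins (31 and 14 of 65, 32 and 14 over the list alone, 0.00287). For these the adjusted p were 0.549, 0.538 and 0.538 with an estimated correlation. Secondary metabolism was higher (21 higher and 5 lower of 37, 21 and 7 over the list alone, 0.0306), with adjusted p = 0.549 with an estimated correlation. Hemicellulose degradation was lower (36 and 26 of 83, 36 and 27 over the list alone) and secreted proteases higher (25 and 6 of 48, the same over the list alone), both at an adjusted p of 0.0471, and at adjusted p = 0.549 and 0.538 with an estimated correlation. These calls were lost with trimmed mean factors (0.138 and 0.0794), with equal medians (0.145 and 0.0793) and with a pseudocount of 0.1 (0.0502 for both), and that of hemicellulose also with quantile normalization (0.115) and with no filter (0.0797). Leaving out clrB deletion replicate 3 (0.0797 and 0.0579) or rcoA deletion replicate 1 (0.0696 and 0.0568) ended both. The hemicellulose call also ended without clrB deletion replicate 1 (0.0897), and the protease call without rcoA deletion replicates 2 and 3 (0.0588 and 0.0545). The others were not called (adjusted p from 0.152 to 0.7). Higher and lower members numbered 14 and 5 for starch, 9 and 10 for pectin, 33 and 20 for cell wall (34 and 21 over the list alone), 8 and 2 for cytochrome P450, 3 and 1 for asexual development and 5 and 8 for glycolysis. They numbered 10 and 11 for ER folding (9 and 5 over the list alone), 19 and 10 for DNA replication and histones (15 and 9), 21 and 15 for nitrogen uptake (22 and 15) and 1 and 2 of 4 for the untested sugar transport list, and those with no second pair were the same over the list alone. For ER folding the median lay below 0 and the mean above, with camera downward. In all, 3204 genes were higher and 2266 lower. The share higher, 58.6%, was 48.6% with trimmed mean factors, 46.2% with equal medians and 45.3% with quantile normalization, and the median log2 difference of all genes moved from 0.108 to -0.0523 with the latter.

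Many genes changed in both deletions. In the same direction 722 rose and 509 fell, against 373 and 258 for independent lists of these sizes. With trimmed mean factors 535 rose and 660 fell, with equal medians 601 and 600, and with quantile normalization 614 and 637, so the excess of shared rises over shared falls depended on the scaling. Simulations of unchanged strains sharing their controls gave 0 such calls on average over 100 draws, a count that the error control holds near 0. The share of all tested genes with the same sign was 64.5%, against 66.6% in the simulations. In opposite directions, 206 were higher in the clrB deletion and lower in the rcoA deletion and 104 the reverse, against 420 and 230 for independent lists. The correlation of log2 changes was 0.282 across genes, which are not independent replicates, against 0.496 in the simulations. In unchanged strains that share controls, this correlation and the share of genes with the same sign are set by the design. Values below the simulated ones therefore do not show that the deletions agree less than unchanged strains. The covariance was 0.206 against 0.0184 in the simulations. The 3 wild type libraries could not be split into parts of 2, so part of the overlap may come from the shared controls. A cellulose monooxygenase (PDE_01261) fell 71.6-fold in the clrB deletion, or 128-fold without clrB deletion replicate 2, and 113-fold in the rcoA deletion, and Cel6A and the HSP20 gene PDE_02505 changed most in both by the same measure. The endoglucanase PDE_06439 fell 8.87-fold in the clrB deletion (14.2-fold without replicate 2) and rose 4.54-fold in the rcoA deletion, and PDE_03882, with no description of function, and PDE_02342, described as a pappalysin, rose 5.62-fold and 6.58-fold in the clrB deletion and fell 7.89-fold and 4.84-fold in the rcoA deletion. The clrB calls of PDE_03882 and PDE_02342 were lost under 8 and 10 of 19 alternatives and the rcoA call of PDE_02342 under 6, and clrB deletion replicate 2 read 42.2 and 25.6, against up to 41.4 and 24.0 in wild type. The 1231 genes changed the same way became 2013 without clrB deletion replicate 2, 492 without replicate 3, and 561 and 665 without wild type replicates 1 and 2.

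**Figure D4:**
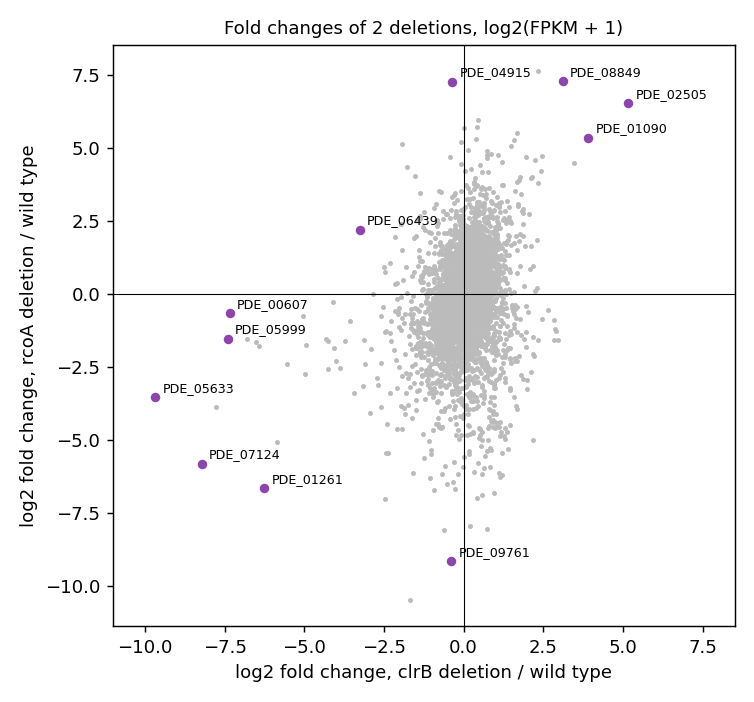
Log2 fold change on the log2(FPKM + 1) scale of each tested gene (grey) in the clrB deletion (horizontal axis) and the rcoA deletion (vertical axis) against wild type, with 11 named genes in purple. PDE_02505 lies at 5.17 and 6.53, PDE_05633 at -9.68 and -3.53, and PDE_09761 at -0.38 and -9.14.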

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

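The tests in this part were chosen after the result was seen, except the test of the closed sum and the other splits of the libraries, which were fixed before their values were computed. In both deletions 310 genes were called with opposite directions, and the limma call of the difference between the deletions in all 310 follows from that choice of genes and adds no evidence.

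Replicate 2 of the clrB deletion lay away from replicates 1 and 3, and at 685 genes that differed at least 2-fold between those replicates and wild type its values needed a median share of 0.679 of wild type (quartiles 0.183 and 0.976). Wild type RNA in this library is argued against: at 11 genes abundant in wild type and near silent in replicates 1 and 3, the median share of the wild type level was 8.11e-05 (quartiles -0.000229 and 0.00977). RNA of the rcoA deletion is argued against by a median share of 0.00305, though over only 3 genes. A lower depth adds noise in both directions and is argued against, since replicate 2 lay on the wild type side at 87.3% of the 685 genes, while with genes chosen on replicate 1 or 3 alone the remaining one of that pair lay there at 63.7% or 52.5%. A difference in culture stays open, and no biological explanation was tested.

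More genes were higher than lower in the clrB deletion. The cellulose list held 3.01% to 4.12% of all FPKM in wild type and 0.227% to 0.484% in the clrB deletion, and a fall of abundant transcripts raises the FPKM of others. The 10 genes with the highest FPKM in each library held 13% to 13.4% of all FPKM in wild type and 16.4%, 13.4% and 16.1% in clrB deletion replicates 1, 2 and 3, so other abundant transcripts took up share in replicates 1 and 3. With trimmed mean factors the share of calls that were higher was 45.7%, but such factors centre the log2 changes, so this decides nothing and the closed sum stays open. Replicate 2 as the source is argued against, since without it the share was 64.4%.

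Genes changed the same way in both deletions more often than independent lists would. The shared wild type libraries alone are argued against by the covariance of 0.206, against a highest value of 0.0211 in 100 simulations. A covariance gives most weight to genes with large changes. Part of the count of genes changed the same way may therefore still come from the shared controls. The correlation (0.282 against 0.496) and the share of genes with the same sign (64.5% against 66.6%) did not exceed the simulated means. In unchanged strains sharing controls both are set by the design, whatever the size of the changes, so they do not decide this. The wild type libraries may still differ from both deletion strains for reasons other than the deleted genes, such as strain construction or culture, which no library here separates. A shared biological response to both deletions stays open and untested.

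Other splits of the same libraries were counted for each comparison, with 10 splits in each, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes as observed. The clrB deletion against wild type called 1987 genes, and the highest of the other splits called 1. The rcoA deletion against wild type called 5866 and the clrB deletion against the rcoA deletion 5470, with 0 as the highest of the other splits in each. Each of the other splits put libraries of both strains in each group, so a strain difference widened the spread within groups. Few calls are then forced whenever the strains differ, so these counts are no measure of chance.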

How the results depend on the processing

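The 19 alternatives for the counts of genes were planned before the data were examined. No called gene given by the naming rule, and no called list among those fixed beforehand, reversed in any of them. The genes, list and terms chosen after the data were seen were not run through the alternatives. The direction held by most calls turned with the scaling in each comparison. Calls in the clrB deletion numbered 1274 with only the libraries of both groups in the fit, against 1987, and ranged from 724 to 3409 when single libraries were left out. In the same way calls ranged from 5118 to 6393 in the rcoA deletion, from 4551 to 5671 between the deletions, and from 492 to 2013 for genes changed the same way in both. Each of these fits holds fewer libraries, but this does not account for the highest counts, which all came without clrB deletion replicate 2. Deviations from the group mean were widest in that library (standard deviation 0.378, against 0.107 to 0.253 in the others). The 3 strains share 1 estimate of the spread in the fit. The cause was not tested further. Lists called by camera ranged from 5 to 7 in the clrB deletion, from 5 to 6 in the rcoA deletion and from 5 to 7 between the deletions when single libraries were left out. With an estimated correlation 0 lists were called in each comparison. With fry, which does not compare a list with other genes, 14 were called in the rcoA deletion and 14 between the deletions, against 5 and 7. Deviations of same-numbered libraries from their group means correlated from -0.161 to 0.341, so not every pair deviated together and the numbers were not taken to pair the libraries. With the replicate block 1725, 5803 and 5380 genes were called in the clrB, rcoA and direct comparisons and 1091 changed the same way. Tests on counts were not run, because the values are FPKM. Depth limits low genes most, and the total reads behind each library are unknown.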

Other observations

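The gene ontology terms, the sugar symporter list and the tests of gene order in this part were chosen after the data were seen. Of 31 genes of ribosome biogenesis 21 rose and 0 fell in the clrB deletion (median log2 change 0.66, camera adjusted p = 7.27e-06) and 25 rose and 0 fell in the rcoA deletion (median 1.27, adjusted p = 3.23e-07). The adjusted p were 0.736 and 0.745 with an estimated correlation. Among 34 genes of tRNA aminoacylation 12 rose and 0 fell in the clrB deletion (adjusted p = 0.00119, and adjusted p = 0.736 with an estimated correlation), and 14 rose and 2 fell in the rcoA deletion, where the term was not called (adjusted p = 0.0536). Of 57 genes described as sugar symporters of the SP family 11 fell and 7 rose in the clrB deletion and 25 fell and 14 rose in the rcoA deletion, with no camera call (adjusted p = 0.0919 and 0.233).

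Genes with consecutive locus numbers changed together. Across 8437 pairs of tested genes with consecutive numbers, the correlation of log2 changes was 0.329 in the rcoA deletion and 0.288 in the clrB deletion, against at most 0.0467 and 0.0422 in 1000 shuffled orders. The longest unbroken run of genes lower by at least 2 log2 units in the rcoA deletion held 16 genes, from PDE_00794 to PDE_00809, against at most 5 in the shuffled orders. In it PDE_00794, described as verruculogen synthase, went from 83.4 to 0.08 FPKM and PDE_00797, described as a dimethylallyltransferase, from 61.4 to 0.03, and these are types of enzyme that make indole alkaloids. In the clrB deletion their means were 202 and 124. The longest such run in the clrB deletion held 3 genes, no more than in the shuffled orders. Reads shared between overlapping neighbours were not tested. The 4 genes from PDE_09758 to PDE_09761 fell together too, with log2 changes of -6.49, -6.43, -6.15 and -9.14. Of the genes in this paragraph all but PDE_09761 were chosen after their values were seen.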
